A study of Homo sapiens with 12 samples.

How the data were processed

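MicroRNA signal was measured on 12 arrays in human brain microvascular endothelial cells (HBMVECs), the primary cells that line the capillaries of the brain. The labels put 6 of the arrays in cells cultured alone and 6 in cells kept for 24 h with U87-CFP cells, the established human glioma line U-87 MG marked with a cyan fluorescent protein. Each group held 3 samples, described as biological replicates, and each sample was run on 2 arrays. Per the labels' protocols, endothelial cells were recovered with beads against CD31, an endothelial surface protein, and judged over 99.9% free of glioma cells by microscopy. The fraction of RNA under 60 nt was taken from 10 micrograms of total RNA and end-labelled with radioactive phosphorus. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples.

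The deposited values were linear intensities, 1 column per array, in a table of 432 rows. Of these, 23 rows were named as background spots and 409 were probes with identifiers of the form ELPS and a number. The image analysis, the background correction and any scaling by the authors are not given in the sources used here. Between 49 and 155 of the 409 probes stood at exactly 1 on each array, and few values lay below 1. Array medians ranged from 18.7 to 89.0, so the table had not been brought to one level. No 2 arrays held identical values.

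The table used here pairs no probe with a microRNA name, and 0 of the 409 identifiers were found in the reference gene table. Probes are therefore reported by identifier, at most 2 in each direction, and genome positions are not given. The 21 lists of microRNAs fixed before the data were examined, which covered angiogenesis, hypoxia, inflammation, microRNA families and markers of glioma, neural, blood, muscle and epithelial cells, could not be matched and were not tested. Whether any ELPS probe is a control is not known, and all 409 were tested.

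Values below 1 (29 of them, 11 at or below 0) were raised to 1, the 10th percentile of the positive values. Log2 values of the 409 probes were quantile normalized between arrays with limma 3.58.1 in R 4.3.3, and the 2 arrays of a sample were averaged and counted as 1 replicate. Quantile normalization gives all arrays one distribution, so it removes any overall rise or fall in signal and leaves the brightest probe of every array at one level. Tied values received the mean of their ranks, which sets the many values of 1 at a different level on arrays that hold more of them. Groups were compared with lmFit and eBayes (limma), two-sided, without covariates, with Benjamini-Hochberg adjustment over the 409 probes and a threshold of 0.05. The design fixed before the data were examined was kept with exceptions. It raised values at or below 0 after scaling, whereas all values below 1 were raised here before quantile normalization. Its set tests had no names to work on. Its rule for naming probes left out those without a microRNA name, and was applied to identifiers instead. That rule took the probes past the adjusted threshold and, where there were none, those with the smallest unadjusted p whose 3 samples of one group all lay above all 3 of the other. The first 2 in each direction are named.

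The level that separates signal from background was set, after the data were seen, at the 95th percentile of all background spots, an intensity of 52.3. A probe not above it on any array of a group has only a bound there. Such a fold is written as at least N-fold, from the mean of the brighter group against, on each array of the dimmer group, the higher of the probe's own value and the lowest value among probes above background. Values per sample were compared with exact permutation tests. With 3 samples against 3, a two-sided exact test cannot give a p below 0.10. Precision is limited by the number of arrays, and no count of molecules lies behind an intensity.

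The fit was tested on simulated data drawn from the means and spreads of the 409 probes, in 20 sets. The noise was normal with the same SD in both groups, and the 2 arrays of a sample were identical. No floor, ties at 1 or sample of low signal was included, so the shares below may not hold for the real data. Of the probes changed by 3 on the log2 scale, 72.0% were at an unadjusted p under 0.05 and 12.5% passed the adjusted threshold. For a change of 2 these shares were 51.2% and 3.0%, for a change of 1 they were 20.2% and 0.50%, and for unchanged probes they were 6.10% and 0.072%. Alternatives covered the normalization, the floor or pseudocount, filters on dim probes, single arrays, the 12 arrays with the sample as a random block, the replicate number as a block, other variance estimates, and each sample left out in turn. A floor at the background level, applied to the normalized values, and another treatment of ties were added after the data were seen. Normalization shifts values, so a value below background as deposited can stay above that floor, and the reverse can hold.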

Results

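The comparison asked how the microRNA profile of brain microvascular endothelial cells differed after exposure to U87 glioma cells. It held 3 samples of HBMVECs cultured alone and 3 samples of HBMVECs recovered from co-culture, each on 2 arrays of 409 probes. The summed intensity of an array ranged from 191283 to 258789 in cells cultured alone. In exposed cells it ranged from 200594 to 278350 in replicates 1 and 3, and was 52644 and 81895 on the 2 arrays of replicate 2.

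**Figure D1:**
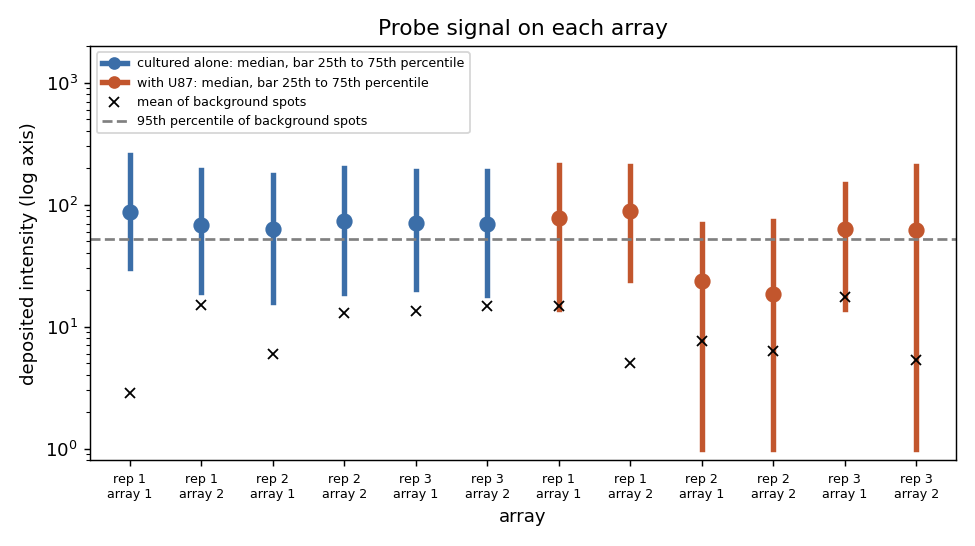
Deposited intensity (log axis) of the 409 probes on each of the 12 arrays, with the median as a point and the 25th to 75th percentile as a bar; crosses mark the mean of the 23 background spots and the dashed line their 95th percentile over all arrays. Both arrays of exposed replicate 2 have medians of 23.9 and 18.7, below those of the other 10 arrays.

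Signal was spread unevenly over the probes in both groups. One probe was the brightest on all 12 arrays and alone gave 12.2% to 22.0% of an array's summed intensity. The 20 brightest probes of an array together gave 64.4% ± 3.89 (SD, n = 3) in cells cultured alone and 67.9% ± 0.91 (SD, n = 3) in exposed cells. For the share of the brightest probe and for that of the 20 brightest, the exact permutation test gave a two-sided p of 0.30 (0.60 after Benjamini-Hochberg adjustment over 5 measures), where 3 samples against 3 cannot give less than 0.10. A total of 67 probes exceeded the background level of 52.3 on all 12 arrays, and 20 exceeded it on none.

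The number of probes above background was 238 ± 11 (SD, n = 3) in cells cultured alone and 204 ± 62.6 (SD, n = 3) in exposed cells. The wide spread of the second value came from exposed replicate 2, with 135 probes, against 258 and 218 in the other two (means of 2 arrays). The median log2 intensity was 6.16 ± 0.09 (SD, n = 3) in cells cultured alone and 5.58 ± 1.04 (SD, n = 3) in exposed cells. The difference was -0.58 (exact permutation test, two-sided p = 0.60), and without exposed replicate 2 it was 0.01. The background spots averaged 10.8 ± 2.84 (SD, n = 3) and 9.44 ± 2.24 (SD, n = 3), in unexposed and exposed cells (exact permutation test, two-sided p = 0.60).

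No single probe passed the adjusted test. After normalization, all 3 exposed samples lay on one side of all 3 unexposed samples for 92 of the 409 probes, 51 of them higher and 41 lower in exposed cells. Chance gives 10% of independent probes, or 40.9, but probes are not independent and 3 samples against 3 are too few to exclude chance. Some of the 92 never exceeded the background, and the unlike level of tied values of 1 can separate such probes. The count was 74 with normalized values raised to the background level and 89 with ties not averaged. The number of probes at an adjusted p under 0.05 was 0 (limma, Benjamini-Hochberg, smallest adjusted p = 0.22). At an unadjusted p under 0.05 there were 50 probes, where 20.4 are expected by chance among independent probes, and 46 of them showed no overlap between the groups. Without unexposed replicate 1 the 50 became 29, and without unexposed replicate 2 they became 31. Without exposed replicate 2, the sample of low signal, they were 53.

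The 50 probes comprised 29 with lower signal in exposed cells and 21 with higher signal. Of these 50 probes, 4 exceeded the background level on all 12 arrays. They were lower by 4.95-fold and 4.27-fold (2.57-fold and 2.68-fold without exposed replicate 2) and higher by 2.57-fold and 2.97-fold in exposed cells, with limma adjusted p of 0.32 to 0.39. Of the 50, 16 did not exceed the background on any array of at least one group, so they have no exact fold. The number of probes at exactly 1, a frequent low value, was 49 to 73 on unexposed arrays. It was 132 and 155 in exposed replicate 2 and 120 on array 2 of exposed replicate 3, and 62 to 75 on the other 3 exposed arrays. The share of higher probes was thus 42.0%. It moved with the setting, to 30.4% (14 higher and 32 lower) with median centring, 26.8% (11 higher and 30 lower) with centring on the 75th percentile, and 2.9% (1 higher and 33 lower) without normalization. It rose to 62.5% (30 higher and 18 lower) in a plain test without moderated variances, and to 57.8% (37 higher and 27 lower) with values raised to the background level and without exposed replicate 2. Without normalization the median of all probes shifted by -0.68 on the log2 scale. The higher and lower probes also differed in brightness. Of the 29 lower probes, 17 had a mean normalized signal above the background level and 22 exceeded it as deposited on all 6 arrays of unexposed cells. Of the 21 higher probes, 4 had a mean normalized signal above the background level and 2 exceeded it as deposited on all 6 arrays of exposed cells. The counts over all 6 arrays are not on equal terms. The arrays of exposed replicate 2 had 131 and 139 probes above background, against 227 to 265 on unexposed arrays.

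**Figure D2:**
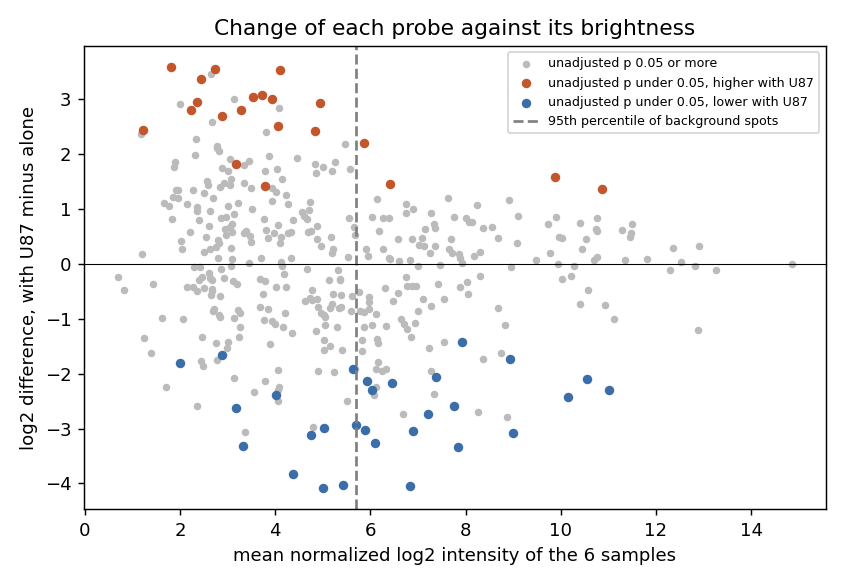
Log2 difference (exposed minus alone) of each of the 409 probes against its mean normalized log2 intensity over the 6 samples; coloured points are the 50 probes at an unadjusted limma p under 0.05, and the dashed line is the 95th percentile of the background spots. Of the 21 higher probes, 17 lie at or below that line, against 12 of the 29 lower probes.

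Grouped by brightness, a choice made after the data were seen, non-overlapping probes were most frequent among those with clear signal. Of the 102 brightest probes, with mean normalized intensities of 120 or more, 40 showed no overlap between the groups, 20 higher and 20 lower in exposed cells, where chance gives 10.2. The split was 19 higher and 24 lower with median centring, 13 and 24 with centring on the 75th percentile, and 0 and 19 without normalization. Estimated differences of over 2-fold among these 102 comprised 23 probes lower and 5 higher in exposed cells, and 35 lower and 0 higher without normalization. Without exposed replicate 2 these were 17 lower and 5 higher. They were 27 lower and 10 higher without exposed replicate 1, and 22 lower and 10 higher with array 2 only. At an unadjusted p under 0.05 stood 11 lower and 2 higher probes of the 102. Among the next 102 probes by brightness 23 did not overlap, among the following 102 it was 15, and among the 103 dimmest it was 14.

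The 20 probes with the highest mean signal were looked at separately. These probes all had mean normalized intensities of 1737 or more, their median log2 difference was 0.07, and 16 lay within 2-fold. Quantile normalization gives every array the same highest values, so it largely sets this median, and the brightest probe cannot differ between samples. For the 102 brightest probes the median log2 difference was 0.06 with normalization. It was -0.51 without normalization, where the low signal of exposed replicate 2 counts. Of the 4 among the 20 that differed by over 2-fold, 3 were lower and 1 was higher in exposed cells. The extremes of the 20 were -2.31 and 1.36 on the log2 scale. The probe at -2.31 is the one given above as 4.95-fold lower, or 2.57-fold without exposed replicate 2. At an unadjusted p under 0.05 stood 1 lower and 1 higher probe of the 20.

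The probe with the smallest p was ELPS-77, which lay above background in unexposed cells only. Its deposited intensity was 65.1 to 119 on the 6 arrays of cells cultured alone and 1 to 27.4 on the 6 arrays of exposed cells, none of which lay above background. It was at least 1.44-fold lower in exposed cells. The fit gave an unadjusted limma p of 0.0014 and an adjusted p of 0.22. With normalized values under the background level raised to it, the log2 difference of ELPS-77 was -0.57 (limma adjusted p = 0.24). This too is a bound, since its exposed values then stood at the floor. ELPS-77 was the one probe above background on all 6 arrays of unexposed cells and on 0 of 6 arrays of exposed cells, and no probe showed the opposite. The opposite needs signal on the arrays of exposed replicate 2, where 131 and 139 probes lay above background, against 227 to 265 on unexposed arrays. The 2 directions are therefore not on equal terms.

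ELPS-109 was the second named probe with lower signal in exposed cells. It gave 142 to 328 on the arrays of unexposed cells and 1 to 58.8 on those of exposed cells, where 2 of 6 arrays lay above background. Its fitted log2 difference was -3.03 ± 0.61 (SE, 3 samples per group), with an adjusted p of 0.22 in limma, and its size rests on exposed values that are mostly below background. With normalized values under the background level raised to it, the difference of ELPS-109 was -1.68 and passed the threshold (limma adjusted p = 0.044). Every exposed value then stood at the floor, so -1.68 is a bound set by the unexposed mean. The exposed samples then had no spread, so this p does not measure theirs. Without exposed replicate 2 as well, the bound was by construction again -1.68, with a limma adjusted p of 0.069.

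The 2 probes named for higher signal, ELPS-339 and ELPS-64, lay close to the background. ELPS-339 exceeded it on 1 of 6 arrays of unexposed cells and on 3 of 6 arrays of exposed cells, with a highest intensity of 123. Both of its normalized group means lay below the background level, so no fold or log2 difference is given as its change. Its adjusted p in limma was 0.22, and with values under the background level raised to it the log2 difference was 0.37 (limma adjusted p = 0.11). ELPS-64 exceeded the background on 0 of 6 arrays of unexposed cells and on 2 of 6 arrays of exposed cells, at up to 154. No fold is given for ELPS-64, because the mean of its exposed samples did not exceed the bound for unexposed cells. Its adjusted p was 0.22 in limma. With normalized values under the background level raised to it, the log2 difference was 0.28 (limma adjusted p = 0.51). In exposed replicate 2 its deposited mean was 20.5, yet its normalized log2 value of 5.76 lay above that floor.

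**Figure D3:**
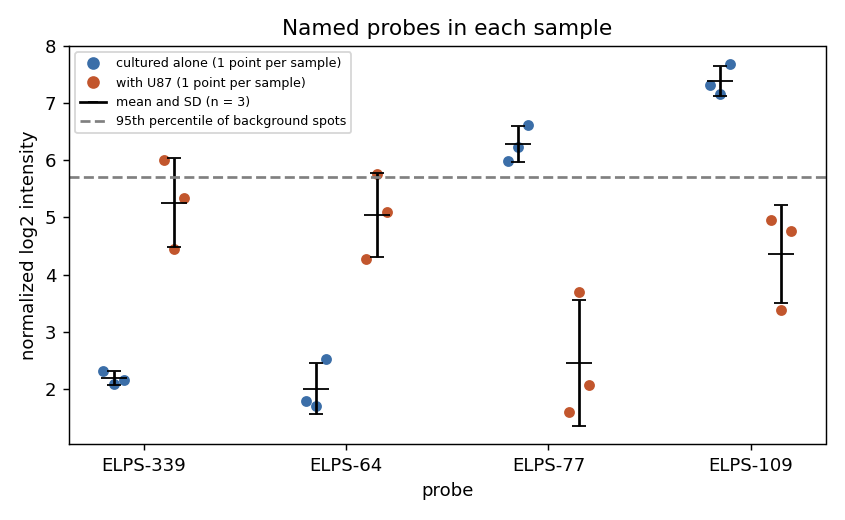
Normalized log2 intensity of the 4 named probes in the 3 samples of cells cultured alone and the 3 exposed samples, 1 point per sample. Bars are the mean and SD, and the dashed line is the background level of the deposited values. The groups do not overlap for any of the 4, and the exposed means of ELPS-339 and ELPS-64 lie below the line.

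The labels do not say whether the 2 arrays of a sample were separate filters or repeated prints, so their difference may cover array-to-array error or the error between spots alone. The SD of the difference between the 2 arrays of a sample, over all probes on the log2 scale, was 2.34, 2.71 and 2.39 in replicates 1 to 3 of unexposed cells and 2.69, 3.20 and 3.11 in exposed cells. Among the 102 brightest probes it was 0.42, 0.51 and 0.43 in unexposed cells, 0.54 in exposed replicate 1, 2.04 in exposed replicate 2 and 1.59 in exposed replicate 3. The correlation of the 2 arrays across these 102 probes, which are not independent replicates, was 0.96 to 0.97 in unexposed samples and 0.96, 0.71 and 0.75 in exposed samples.

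Across the 102 brightest probes, the correlation between samples was 0.92 to 0.95 among unexposed cells, 0.80 to 0.86 among exposed cells, and 0.64 to 0.90 between the groups. The mean correlation within groups exceeded that between groups by 0.11, the largest of the 10 possible splits (exact permutation test, one-sided p = 0.10, the smallest that 3 samples against 3 allow). Over all 409 probes the excess was 0.037 (exact permutation test, one-sided p = 0.10). There, unexposed samples correlated at 0.82 to 0.85 with each other. Exposed samples correlated at 0.65 to 0.77 (median 0.67) with each other and at 0.62 to 0.80 (median 0.77) with unexposed samples.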

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

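The background floor, the treatment of ties and the counts of probes without overlap were chosen after the data were seen. The count of 0 probes at an adjusted p under 0.05 (limma) held in 18 of 22 alternatives. It became 2 with array 1 only and 2 with eBayes using trend and robust settings. With values raised to the background level, which removes spread below that level, it became 5 (4 lower and 1 higher, ELPS-109 among them). With that floor and without exposed replicate 2 it became 1. Leaving out each sample in turn kept it at 0, and a plain t-test on the same values gave 0 after adjustment and 48 before. The 50 probes at an unadjusted p under 0.05 ranged from 29 to 56 when 1 sample was left out, and stayed within 1.5 times of 50 in all alternatives except those without unexposed replicate 1 or 2. Fewer of the same probes stayed at that threshold and in that direction. Of the 50 these were 29 with array 1 only, 20 with array 2 only (1 turned), and 24 and 26 without unexposed replicate 1 or 2. Without normalization 24 stayed (1 higher and 23 lower). With the background floor 25 stayed, and 21 with that floor and without exposed replicate 2 (2 turned). The share of higher probes, 42.0%, was 2.9% without normalization, 26.8% with the 75th percentile, 62.5% in the plain t-test and 57.8% with the background floor without exposed replicate 2. The 92 probes without overlap became 58 without normalization and 74 with values raised to the background level. They became 118 to 139 when 1 sample was left out, where chance rises to 20%. The 40 among the 102 brightest probes became 19 without normalization and 41 to 53 with 1 sample left out. The difference in median signal, -0.58, ranged from -0.98 to 0.013 with 1 sample left out, and reversed only without exposed replicate 2. The SD between arrays, with a median of 2.70, was 1.67 over the brighter 204 probes. The 4 named probes kept direction where tested, which their non-overlap mostly fixed. The causes were not tested.

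Samples with the same replicate number shared only that number: their deviations from the group means correlated at -0.03, 0.03 and 0.04 for numbers 1 to 3, and not every sample correlated best with its own number. With the replicate number as a block, 42 probes in place of 50 were at an unadjusted p under 0.05 and 0 passed the adjusted threshold. The tests of microRNA lists, with their alternatives, were not run because the probes carry no names. Between 131 and 265 of the 409 probes exceeded the background level on an array, which limits what can be said of the others.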

Other observations

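The count without exposed replicate 2 was planned before the data were examined, and the other tests in this part, with the bound that count is set against, were chosen after the data were seen.

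The separation of the groups was compared with that of the other ways to split the 6 samples into 3 and 3. The real split gave 50 probes at an unadjusted p under 0.05 and the highest of the other 9 gave 25, so 1 of the 10 splits reached the real count. For probes without overlap the real split gave 92 and the highest other 43, and among the 102 brightest probes 40 against 9. The 10 splits are too few to give a share under 0.05. The adjusted count cannot be tested in this way: its real value was 0, which 10 of 10 splits reach by construction (highest other 0). A candidate explanation for the excess was the sample of low signal, exposed replicate 2. Without it the count was 53, so the count did not rest on that sample alone. This is above the 29.3 that chance with 2 binomial SD allows for independent probes. Probes are not independent, and without unexposed replicate 1 the count was 29, so the bound cannot name a source. An effect of the co-culture and a difference in handling between the groups remain open and untested. The labels do not settle whether the cells cultured alone were kept in the same medium as the co-cultures, and without probe names no marker of another cell type could be followed.

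Many of the probes higher in exposed cells were dim, with the mean normalized signal of 17 of 21 at or below the background level. Noise of values near the background may account for them. Put through the same normalization and fit, 0 of the 23 background spots were at an unadjusted p under 0.05, with an exact binomial interval up to 14.8%, against 12.2% of the probes. The spots are too few to exclude noise. Of the 21 higher probes, 7 stayed at an unadjusted p under 0.05 once values were raised to the background level, against 18 of the 29 lower ones. With that floor 29 higher and 31 lower probes in all stood at that threshold. The floor itself shrinks the differences of probes at or below it, so the kept counts do not decide whether noise was the source.

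Exposed replicate 2 had a median signal of 21.3 against 62.5 to 83.3 in the other 5 samples. Failure of 1 of 2 separate filters could not account for it, since 2 of its 2 arrays had medians below the lowest of the other 10. The labels do not say whether the 2 arrays were separate filters, so a failure shared by the 2 stays open. Whether a difference of scale alone, as from less labelled RNA, is enough was not settled. After normalization, its deviations from the other exposed samples over the 40 brightest probes had an SD of 0.81. The other 5 samples had 0.40 to 0.72. The value of 0.81 lies above that range and below 1.5 times its highest, so it decides nothing. Over the 102 brightest probes, the SD of the difference between its 2 arrays was 2.04. It was 0.42, 0.51 and 0.43 in unexposed cells and 0.54 in exposed replicate 1. Exposed replicate 3, which did not have low signal, had 1.59, so this measure does not decide either. No biological explanation was tested, since the design names no difference between replicates.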
